A study of Mus musculus with 6 samples.

How the data were processed

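Poly(A) RNA-seq of the mouse cell line NE-4C was analysed in 6 libraries, 2 in each of 3 groups, H3.3WT, Cbfa2t2_KO and H3.3K27M, as the sample labels name them. RNA was extracted with Trizol, mRNA was captured on oligo(dT) beads and primed at random, and the labels do not state the strand of the libraries. The values are FPKM as deposited by the authors, in 1 table for Cbfa2t2_KO with H3.3WT and 1 for H3.3K27M with H3.3WT. The labels list Trim Galore, HISAT2, StringTie and DESeq and the build GRCm38, without versions, and the annotation release is not stated. The tables hold 14431 and 14318 genes, and in each table every gene had at least 0.500 FPKM in at least 1 library, so genes below that level are not seen. No counts are in the tables. The lowest values were not whole multiples of a step (highest share 0.255 to 0.315, with a tolerance of 0.1), so the depth is unknown and no counting interval was computed. Summed FPKM ran from 363586 to 419389 over the libraries of both tables.

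Columns were matched to groups by their names. The columns used for H3.3K27M carry only the letter M, and their replicate numbers follow the column order within the group. Replicate numbers of the other groups follow the order of the sample records and pair no libraries across groups.

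Genes were keyed by Ensembl ID. GENCODE vM21 held 14646 of the 14667 IDs in at least 1 table, 14401 with the same symbol, and supplied coordinates, exon numbers, transcript length and GC content. Genes with a mean of at least 1 FPKM in the libraries of a comparison were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, eBayes with trend), and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Each line was compared with H3.3WT in a fit of 4 libraries, and H3.3K27M with Cbfa2t2_KO in a fit of all 6. With 2 against 2 libraries an exact two-sided permutation test cannot give a p below 0.333, so limma, which pools the spread over genes, was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

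The comparisons, 42 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists of mitochondrially encoded genes, cytosolic ribosomal proteins, replication-dependent histones and immediate early and heat shock genes were meant as checks of RNA quality. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Camera at an estimated correlation rests on the 2 or 3 residual degrees of freedom of a fit and has low power here. The rule named Cbfa2t2, H3f3a and H3f3b, then the 10 largest rises and the 10 largest falls (5 and 5 for H3.3K27M against Cbfa2t2_KO) among genes past the threshold, with groups that did not overlap and at least 2 FPKM in the higher group, without unnamed gene models. It also named 3 members of each of the up to 6 called lists with the smallest p. Trp53 was not analysed here. Correlation and covariance of fold changes between lines were set against 100 simulations of unchanged groups that shared controls, and shared calls against independent lists.

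The procedure was tested on simulated data. At the spread of Cbfa2t2_KO and H3.3K27M against H3.3WT, 87% and 84% of 2-fold changes were recovered. There were 12 false calls of 199 and 16 of 200. Genes were drawn independently there, so false calls from trends across a library are not covered. Alternatives covered the pseudocount (0.1), the filter (none, 0.1 or 5 FPKM), median-of-ratios scaling, quantile normalization, eBayes without trend or robust, a fit of all 6 libraries, a log2 change of at least 1, and leaving out each replicate. Corrections of each library's trend on GC content, length and exon number, and an overlap with a separate H3.3WT library for each line, were added after seeing the data. Protein-coding genes with at most 3 exons were compared with those of at least 6, with bootstrap intervals from 1000 resamples.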

Results

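RNA was measured in 6 poly(A) RNA-seq libraries of NE-4C, a mouse cell line that the labels describe as neural stem cells lacking p53. In every line the H3f3a gene, a source of the histone variant H3.3, had been knocked out, and a tagged H3.3 was then stably expressed. The 3 groups held 2 libraries each. H3.3WT carried tagged wild-type H3.3, Cbfa2t2_KO carried the same protein after a further knockout of the corepressor gene Cbfa2t2, and H3.3K27M carried H3.3 with lysine 27 replaced by methionine, the substitution found in diffuse midline gliomas. The series title links CBFA2T2 to H3K27me3 demethylation and to metabolic genes, and the comparisons asked how RNA levels differed between the lines. Values were FPKM in 2 tables, with 14431 genes for the pair of Cbfa2t2_KO and H3.3WT and 14318 for the pair of H3.3K27M and H3.3WT. The H3.3WT values were identical in both tables for all 14082 shared genes. The columns used for H3.3K27M carry the letter M and no sample name, and were assigned on that letter. Read depth is unknown, because the tables hold no counts, so no counting interval is given. Across the 14082 shared genes, log2 values of libraries of the same group had a Pearson correlation of 0.984 to 0.988. Libraries of Cbfa2t2_KO or H3.3K27M against H3.3WT had 0.945 to 0.957, and Cbfa2t2_KO against H3.3K27M 0.967 to 0.978. Genes are not independent replicates, and these correlations describe the libraries. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are the mean and SD of 2 libraries per group (n = 2), and log2 changes come from limma on log2(FPKM + 1) with their SE, a scale that understates the change of low genes.

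The targeted genes were examined first. Cbfa2t2 (ENSMUSG00000038533; GRCm38 chromosome 2, 154436481 to 154539356, forward strand, up to 11 exons in a transcript) was low in all libraries. It stood at 1.36 ± 0.020 FPKM in H3.3WT, 0.897 ± 0.18 in the libraries labelled Cbfa2t2_KO and 1.44 ± 0.82 in H3.3K27M. The difference between Cbfa2t2_KO and H3.3WT was -0.32 ± 0.16 on the log2 scale and did not pass the test (adjusted p = 0.153). Where in the gene the edit lies is not given in the sources used here, and a gene-level value can stay up after a frameshift, so this value neither shows nor excludes the knockout. H3f3a (ENSMUSG00000060743; chromosome 1, 180800832 to 180813943, reverse strand) stood at 156 ± 35 FPKM in H3.3WT, 74.2 ± 11 in Cbfa2t2_KO and 72.0 ± 7.4 in H3.3K27M. It was lower than in H3.3WT by a log2 change of -1.05 ± 0.19 in Cbfa2t2_KO (adjusted p = 0.0050) and -1.09 ± 0.20 in H3.3K27M (adjusted p = 0.0071). The second of these calls was lost without H3.3WT replicate 2 (adjusted p = 0.067). Whether reads of the introduced H3.3 were counted at H3f3a was not tested, so its value cannot be assigned to the edited locus alone. H3f3b (ENSMUSG00000016559; chromosome 11, 116021912 to 116027962, reverse strand), the other gene that encodes H3.3, stood at 186 ± 21 FPKM in H3.3WT, 145 ± 13 in Cbfa2t2_KO and 128 ± 10 in H3.3K27M. Its differences from H3.3WT did not pass (adjusted p = 0.095 and 0.056), and quantile normalization gave adjusted p = 0.044 and 0.021. Trp53 was not analysed here.

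**Figure D1:**
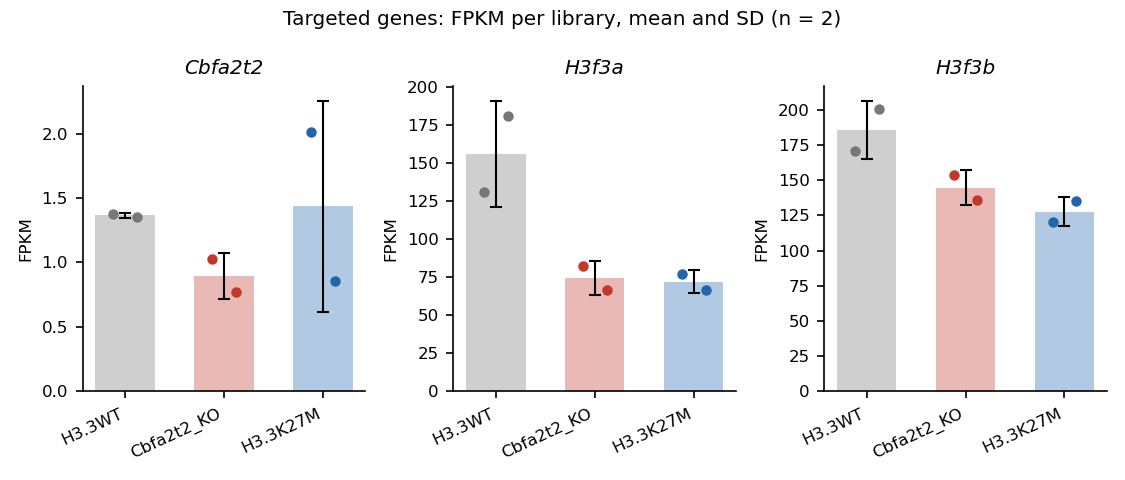
FPKM of Cbfa2t2, H3f3a and H3f3b (y axes, starting at 0) in the 3 groups (x axes); points are libraries, bars the mean and error bars the SD of 2 libraries. H3f3a was 156 FPKM in H3.3WT and 74.2 and 72.0 in Cbfa2t2_KO and H3.3K27M, while the libraries of Cbfa2t2 in H3.3K27M lay at 2.02 and 0.856.

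The first comparison asked what differed after Cbfa2t2 knockout. In the libraries labelled Cbfa2t2_KO, 13 of 18 tested hypoxia and HIF targets, 16 of 24 glycolysis genes, 14 of 24 cholesterol biosynthesis genes, 7 of 16 fatty acid synthesis genes and 11 of 27 TCA cycle genes rose against H3.3WT. In the same libraries 11 of 16 immediate early and heat shock genes fell. So did 16 of 23 tested members of a list of 82 developmental regulators known as Polycomb targets. The calls of these lists by camera were all lost with an estimated correlation (adjusted p = 0.564 or 0.647 with an estimated correlation). Slc2a3 and Slc2a1, which encode glucose transporters, rose from 137 ± 0.44 to 402 ± 11 FPKM and from 166 ± 6.3 to 344 ± 14. Cdkn2a, which encodes cell cycle inhibitors and is a textbook Polycomb target (chromosome 4, 89274471 to 89294653, reverse strand), rose from 6.63 ± 0.036 to 56.8 ± 4.9 FPKM, a ratio of means of 8.57 (log2(FPKM + 1) change 2.92 ± 0.14, adjusted p = 0.00011). Egr1, an immediate early transcription factor (chromosome 18, 34859823 to 34864984, forward strand), fell from 223 ± 71 to 7.57 ± 0.031 FPKM (log2 change -4.67 ± 0.21, adjusted p = 9.8e-05). The immediate early and heat shock list had been chosen as a check of RNA quality. Egr1 also fell in H3.3K27M, so handling of the shared H3.3WT libraries cannot be told apart from a change in both lines. The same limit holds for the rises of the metabolic lists, as far as both lines share them. In H3.3K27M the medians were 0.96 for hypoxia, 0.71 for glycolysis, 0.86 for cholesterol, 0.76 for fatty acid synthesis and 0.40 for the TCA cycle.

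In the hypoxia and HIF target list, 13 of 18 tested members rose, none fell and 5 did not pass (median log2 change 0.69, camera adjusted p = 5.0e-07, adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 14 rose. P4ha1, a collagen prolyl hydroxylase subunit, rose from 8.21 ± 0.74 to 25.7 ± 0.93 FPKM, and Ndrg1 from 8.75 ± 0.17 to 24.8 ± 2.7. In the glycolysis list, 16 of 24 tested gene IDs rose, 1 fell and 7 did not pass (median 0.59, adjusted p = 5.0e-07, adjusted p = 0.647 with an estimated correlation), with the same counts adjusted over the list alone. The 24 IDs include 2 that carry the symbol Aldoa. The glycolysis and hypoxia lists as chosen share Slc2a1, Pfkfb3, Pfkfb4, Ldha and Pgk1, so their results are not separate in either line. The neuronal enolase gene Eno2 rose from 7.77 ± 0.85 to 25.9 ± 4.0 FPKM. Glycolytic genes with many processed pseudogenes, Gapdh among them, may share reads with those copies, and their levels are uncertain. In the cholesterol biosynthesis list, 14 of 24 rose and none fell, with the same counts adjusted over the list alone (median 0.63, adjusted p = 5.0e-07, adjusted p = 0.564 with an estimated correlation). Acat2 rose from 19.9 ± 1.2 to 61.2 ± 1.8 FPKM, Dhcr7, which catalyses the last step of the pathway, from 12.97 ± 0.14 to 24.2 ± 0.36, and Mvd from 27.2 ± 5.4 to 54.7 ± 3.8. In the list of fatty acid synthesis and desaturation, 7 of 16 rose and none fell, and 8 rose adjusted over the list alone (median 0.51, adjusted p = 9.8e-05, adjusted p = 0.647 with an estimated correlation). Examples were Scd2, a desaturase, from 115 ± 11 to 274 ± 39 FPKM, the lipogenic transcription factor gene Srebf1 from 19.2 ± 3.9 to 47.1 ± 1.9, and Acly, the ATP citrate lyase gene, from 49.0 ± 9.0 to 92.6 ± 7.6.

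In the TCA cycle list, 11 of 27 rose and 2 fell, also adjusted over the list alone (median 0.27, adjusted p = 0.00039, adjusted p = 0.564 with an estimated correlation). Idh2, the mitochondrial isocitrate dehydrogenase that makes 2-oxoglutarate, rose from 29.1 ± 3.8 to 81.4 ± 6.8 FPKM, Suclg1 from 10.8 ± 0.15 to 24.9 ± 2.1 and Mdh1 from 55.8 ± 3.9 to 114 ± 6.4. Nuclear genes of oxidative phosphorylation rose in 12 of 39 and fell in 3 (median 0.18, adjusted p = 0.0021, adjusted p = 0.647 with an estimated correlation). The G2/M and mitosis list had 7 of 26 higher and none lower (median 0.33, adjusted p = 0.0012, adjusted p = 0.647 with an estimated correlation), epithelial markers 5 of 9 higher (median 0.87, adjusted p = 0.0061, adjusted p = 0.564 with an estimated correlation), and oncofetal and imprinted growth genes 6 of 13 higher (median 0.42, adjusted p = 0.0099, adjusted p = 0.647 with an estimated correlation). Cytosolic ribosomal protein genes had 6 of 34 higher and 1 lower (median 0.12, adjusted p = 0.015, adjusted p = 0.755 with an estimated correlation), a call lost after correction for GC content and length (adjusted p = 0.061), without H3.3WT replicate 2 (adjusted p = 0.135) and without Cbfa2t2_KO replicate 2 (adjusted p = 0.139). The ribosomal protein median was 0.21 without Cbfa2t2_KO replicate 1 and 0.25 with median-of-ratios scaling. The call of oncofetal and imprinted growth genes was lost without Cbfa2t2_KO replicate 1 (adjusted p = 0.064). Without H3.3WT replicate 2 the medians were 0.13 for the G2/M list, 0.57 for epithelial markers and 0.28 for nuclear oxidative phosphorylation genes, with the calls kept. Nuclear oxidative phosphorylation genes had a median of 0.30 with median-of-ratios scaling. Correction for GC content, length and exon number brought the TCA cycle list to 0.18 and nuclear oxidative phosphorylation to 0.11, also with the calls kept.

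Among lists that were lower, the canonical Polycomb target regulators outside the Hox clusters had 16 of 23 tested members lower, 2 higher and 5 that did not pass (median -0.85, adjusted p = 0.00098, adjusted p = 0.564 with an estimated correlation). Adjusted over the list alone, 17 fell. The list holds 82 genes, and members under the FPKM minimums were not tested, so targets low in both groups are not seen. The median was -0.55 with a mean FPKM minimum of 0.1 and further below 0 with a pseudocount of 0.1. The homeobox genes Gsc, En1 and En2 fell from 3.24 ± 0.54 to 0.367 ± 0.14, from 10.7 ± 2.3 to 2.50 ± 0.34 and from 13.7 ± 0.050 to 4.70 ± 0.16 FPKM, while Cdkn2a, also in this list, rose. Immediate early and heat shock genes fell in 11 of 16 and rose in 1, Ier3 (median -0.92, adjusted p = 0.0021, adjusted p = 0.647 with an estimated correlation). ERK pathway targets fell in 5 of 13 (median -0.49, adjusted p = 0.014, adjusted p = 0.564 with an estimated correlation), a call lost after correction for GC content, length and exon number (adjusted p = 0.175), and their median was -0.33 without Cbfa2t2_KO replicate 2. PRC1 subunit genes fell in 9 of 16 and rose in 1 (median -0.50, adjusted p = 0.020, adjusted p = 0.564 with an estimated correlation). Genes of amino acid transport and the ATF4 response fell in 14 of 29 and rose in 3 (median -0.45, adjusted p = 0.026, adjusted p = 0.647 with an estimated correlation), and this call was lost without H3.3WT replicate 1 or Cbfa2t2_KO replicate 1 (adjusted p = 0.052 and 0.087). Adjusted over the list alone, 9 genes rose and 1 fell in the G2/M list, 3 rose and 1 fell among ribosomal proteins, and 4 rose and 15 fell in the ATF4 list. With an estimated correlation no list was called in any of the 3 comparisons. That setting rests on the 2 or 3 residual degrees of freedom of a fit, so its power is low. Polycomb target regulators in Cbfa2t2_KO had an estimated correlation of -0.032, below the preset 0.01. Their camera p still went from 0.00016 to 0.053. A call lost with an estimated correlation therefore does not by itself show that correlated members had made the call. Fry, which tests each list on its own, called 10, 0 and 3. Of the lists above, fry called hypoxia, TCA cycle, Polycomb targets, epithelial markers, ERK targets, PRC1 and ATF4 in Cbfa2t2_KO. It did not call glycolysis (fry adjusted p = 0.077), cholesterol biosynthesis (0.054), fatty acid synthesis (0.101) or the other lists that camera had called.

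Among the 10 largest rises of named genes, beside Cdkn2a, were Ier3 (8.99 ± 1.4 to 54.7 ± 12 FPKM), Krt8, an epithelial keratin (0.752 ± 0.17 to 8.48 ± 0.13), and Acadvl, an acyl-CoA dehydrogenase of mitochondrial fatty acid oxidation (2.52 ± 0.75 to 16.7 ± 0.83). Derl3 and Sdf2l1, which act in endoplasmic reticulum protein quality control, rose from 0.880 ± 0.27 to 8.83 ± 0.78 and from 30.4 ± 1.6 to 147 ± 21 FPKM. Fetub, Grb7, Sept4 and Lrrc45 completed the set, with log2 changes of 2.29, 2.26, 2.23 and 2.17; with a pseudocount of 0.1 that of Grb7 was 4.23. Beside Egr1, the largest falls included the immediate early gene Ier2 (269 ± 49 to 36.8 ± 4.9 FPKM), Ctgf (9.73 ± 2.4 to 0.132 ± 0.0013), the hormone precursor gene Trh (35.2 ± 2.9 to 3.33 ± 0.41), the troponin gene Tnnt1 (30.2 ± 1.9 to 3.27 ± 0.49), Rrad (11.4 ± 4.2 to 0.705 ± 0.24) and Exosc6 (8.70 ± 2.3 to 0.449 ± 0.55). The mitochondrial tRNA genes mt-Td, mt-Tw and mt-Tm fell, with log2 changes of -4.19, -3.87 and -2.91, although tRNAs lack the poly(A) tails of mRNA and are captured poorly by this library type.

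In all, 4028 of 11626 tested genes differed at the adjusted threshold of 0.05, 1528 higher and 2500 lower, and 1073 of them changed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 70.4% of genes, where chance gives 33.3%. The median log2 change over all genes was -0.11. Median-of-ratios scaling brought this median to -0.0027, and 50.6% of calls were then higher, against 37.9% with the values as deposited, so the excess of lower genes depends on the scaling. The count fell to 1915 without Cbfa2t2_KO replicate 2 and to 2236 without H3.3WT replicate 2.

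Of the remaining lists, none passed camera in this comparison, and the adjusted p-values that follow are from camera except where fry is named. By fry, Notch targets (adjusted p = 0.0073) and Wnt targets (adjusted p = 0.047) passed as lower. Fatty acid oxidation passed fry as higher (adjusted p = 0.023). The metabolic lists had medians of 0.27 for the pentose phosphate pathway (adjusted p = 0.288), 0.19 for nucleotide biosynthesis (adjusted p = 0.056), 0.15 for fatty acid oxidation (adjusted p = 0.053), 0.060 for serine, glycine and one-carbon metabolism (adjusted p = 0.126) and -0.10 for glutamine, glutamate and 2-oxoglutarate metabolism (adjusted p = 0.807, with the test pointing up). Among chromatin lists the medians were 0.042 for PRC2 subunits (adjusted p = 0.602), -0.074 for H3K27 demethylases and related dioxygenases (adjusted p = 0.685, with the test pointing up), -0.098 for the CBFA2T family and its partners (adjusted p = 0.824) and -0.36 for H3.3 genes and chaperones (adjusted p = 0.085). For cell type markers, neural stem and progenitor markers had -0.40 (adjusted p = 0.517), neuronal -0.33 (adjusted p = 0.685), astrocyte 0.21 (adjusted p = 0.685), mesenchymal -0.15 (adjusted p = 0.685, with the mean and the test pointing up) and pluripotency markers -0.058 (adjusted p = 0.972, with the test pointing up). Notch targets had -0.62 (adjusted p = 0.061), Wnt targets -0.39 (adjusted p = 0.381) and TGF-beta and BMP targets -0.35 (adjusted p = 0.824). The G1/S list had -0.010 (adjusted p = 0.517, with the test pointing up), p53 targets -0.017 (adjusted p = 0.685, with the mean and the test pointing up), interferon-stimulated genes -0.059 (adjusted p = 0.685, with the mean and the test pointing up), mitochondrially encoded genes 0.068 (adjusted p = 0.514) and replication-dependent histones 0.075 (adjusted p = 0.685, with the mean of -0.51 and the test pointing down). The lists of Hox genes (4 members), oligodendrocyte (3), endothelial (1), microglial and leukocyte (4) and neural crest markers (3) had fewer than 5 tested members and no test, with medians of -0.66, 0.34, -0.0070, 0.39 and -0.67.

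**Figure D2:**
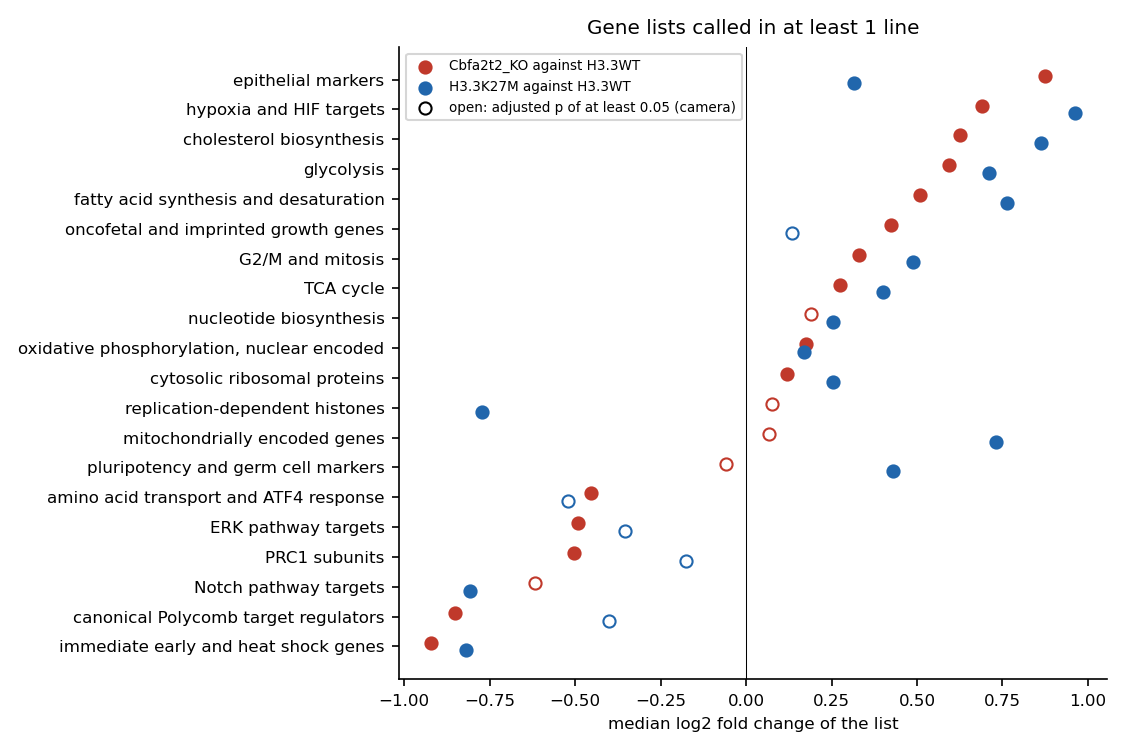
Median log2 fold change (x axis) of the gene lists (y axis) that passed camera in Cbfa2t2_KO or H3.3K27M against H3.3WT, with filled points for an adjusted p below 0.05. Hypoxia and HIF targets had medians of 0.69 and 0.96 and cholesterol biosynthesis 0.63 and 0.86, while immediate early and heat shock genes had -0.92 and -0.82; no list passed with an estimated correlation.

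The second comparison asked what differed with H3.3K27M in place of wild-type H3.3. Against H3.3WT, 17 of 24 cholesterol biosynthesis genes, 14 of 18 hypoxia targets, 13 of 24 glycolysis genes, 11 of 26 G2/M genes and 9 of 13 mitochondrially encoded genes rose, while 5 of 11 replication-dependent histone genes and 7 of 10 Notch targets fell. The calls of these lists by camera were all lost with an estimated correlation (adjusted p = 0.521 with an estimated correlation). Hmgcs1, which encodes the HMG-CoA synthase of the mevalonate pathway (chromosome 13, 119690379 to 119708260, forward strand), rose from 10.6 ± 0.99 to 49.1 ± 1.7 FPKM (log2 change 2.11 ± 0.17, adjusted p = 0.00078). The neuropeptide gene Npy rose most among named genes, from 10.3 ± 2.2 to 75.2 ± 12 FPKM (log2 change 2.75 ± 0.20, adjusted p = 0.00078). Egr1 fell from 223 ± 71 to 6.20 ± 0.32 FPKM (log2 change -4.93 ± 0.22, adjusted p = 9.6e-05). The mitochondrially encoded and histone lists had been chosen as checks of RNA quality. Where a list moved alike in both lines, handling of the shared H3.3WT libraries cannot be told apart here either.

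In the cholesterol biosynthesis list, 17 of 24 tested members rose, none fell and 7 did not pass (median 0.86, adjusted p = 3.5e-13, adjusted p = 0.521 with an estimated correlation). Adjusted over the list alone, 20 rose. Beside Hmgcs1, Acat2 rose from 19.9 ± 1.2 to 71.2 ± 0.15 FPKM and Cyp51, the sterol demethylase gene, from 30.4 ± 4.6 to 88.3 ± 4.8. Hypoxia and HIF targets rose in 14 of 18, and in 15 adjusted over the list alone (median 0.96, adjusted p = 3.6e-11, adjusted p = 0.521 with an estimated correlation). Ndrg1 rose from 8.75 ± 0.17 to 34.7 ± 4.9 FPKM, P4ha1 from 8.21 ± 0.74 to 26.4 ± 3.1 and Ankrd37 from 3.06 ± 0.64 to 11.97 ± 0.93. Glycolysis genes rose in 13 of 24 and fell in 1 (median 0.71, adjusted p = 7.1e-07, adjusted p = 0.521 with an estimated correlation). Eno2 rose from 7.77 ± 0.85 to 25.7 ± 3.2 FPKM, Pgk1 from 355 ± 50 to 748 ± 47 and Slc2a1 from 166 ± 6.3 to 295 ± 14. The call of Pgk1 was lost without H3.3WT replicate 2 (adjusted p = 0.098), and that of Slc2a1 without H3.3WT replicate 1 or 2 (adjusted p = 0.079 and 0.104). Slc2a3 stood at 423.5 and 125.5 FPKM in the H3.3K27M libraries, against 137 ± 0.44 in H3.3WT, and did not pass (adjusted p = 0.248). In the G2/M and mitosis list, 11 of 26 rose and none fell (median 0.49, adjusted p = 8.4e-09, adjusted p = 0.521 with an estimated correlation). The cyclin genes Ccna2, Ccnb2 and Ccnb1 rose from 12.2 ± 0.61 to 30.02 ± 0.50, from 31.9 ± 9.6 to 102 ± 12 and from 16.6 ± 1.4 to 38.7 ± 4.4 FPKM.

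Mitochondrially encoded genes rose in 9 of 13, and in 11 adjusted over the list alone (median 0.73, adjusted p = 7.3e-07, adjusted p = 0.521 with an estimated correlation). The respiratory chain genes mt-Nd1 and mt-Co2 rose from 250 ± 14 to 469 ± 5.2 and from 403 ± 41 to 800 ± 88 FPKM, and mt-Nd6 from 66.5 ± 13 to 118 ± 1.3. Correction for GC content and length brought the list median to 0.42 with the call kept (adjusted p = 0.0020). The same correction brought mt-Nd1 and mt-Co2 from log2 changes of 0.90 and 0.99 to 0.50 and 0.53 (adjusted p = 0.045 and 0.020), and ended the call of mt-Nd6 (0.83 to 0.47, adjusted p = 0.061). Quantile normalization brought mt-Co2 to 0.60 with its call kept. Without H3.3WT replicate 1 all 3 genes lost their calls (adjusted p = 0.099, 0.118 and 0.128). Without H3.3WT replicate 2 mt-Nd1 and mt-Co2 lost theirs (adjusted p = 0.072 and 0.069), and without H3.3K27M replicate 2 mt-Nd6 (adjusted p = 0.052). Fatty acid synthesis and desaturation genes rose in 11 of 16 (median 0.76, adjusted p = 3.0e-06, adjusted p = 0.521 with an estimated correlation), among them Acsl3 (7.04 ± 0.24 to 22.4 ± 2.4 FPKM), Elovl5 (18.003 ± 1.0 to 41.0 ± 3.9) and Scd2 (115 ± 11 to 281 ± 46). Without H3.3WT replicate 2 the median of this list was 0.50. TCA cycle genes rose in 10 of 27 and fell in 2 (median 0.40, adjusted p = 0.00022, adjusted p = 0.521 with an estimated correlation), with a median of 0.16 after correction for GC content, length and exon number. Also higher were the lists of cytosolic ribosomal proteins (6 of 34 rose, median 0.26, adjusted p = 5.3e-05, adjusted p = 0.661 with an estimated correlation), epithelial markers (4 of 10 rose, median 0.31, adjusted p = 0.0028, adjusted p = 0.521 with an estimated correlation) and pluripotency and germ cell markers (3 of 14 rose, median 0.43, adjusted p = 0.011, adjusted p = 0.521 with an estimated correlation). Ribosomal protein genes had a median of 0.51 without H3.3K27M replicate 1, 0.029 without replicate 2 and 0.41 with median-of-ratios scaling. Epithelial markers had 0.20 without H3.3K27M replicate 1 and 0.48 after correction for GC content, length and exon number. Nuclear oxidative phosphorylation genes (5 of 39 rose, 1 fell, median 0.17, adjusted p = 0.0061, adjusted p = 0.661 with an estimated correlation) lost their call after correction for GC content and length (median 0.017, adjusted p = 0.160). Without H3.3K27M replicate 2 their median turned to -0.040 and the call was lost. The median was 0.32 without H3.3K27M replicate 1 or with median-of-ratios scaling, and 0.11 without H3.3WT replicate 1. Nucleotide biosynthesis genes (8 of 24 rose, 2 fell, median 0.25, adjusted p = 0.011, adjusted p = 0.521 with an estimated correlation) lost theirs without H3.3WT replicate 2 (median 0.15, adjusted p = 0.065) and after correction for GC content, length and exon number (adjusted p = 0.054), and had a median of 0.40 with median-of-ratios scaling.

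Replication-dependent histone genes fell in 5 of 11 (median -0.77, adjusted p = 0.0025, adjusted p = 0.521 with an estimated correlation). The linker histone gene Hist1h1c fell from 22.4 ± 3.6 to 2.89 ± 0.10 FPKM. These mRNAs end in a stem-loop instead of a poly(A) tail, so poly(A) libraries capture them poorly. Notch pathway targets fell in 7 of 10 (median -0.81, adjusted p = 0.0025, adjusted p = 0.521 with an estimated correlation), with a median of -0.50 after correction for GC content and length and the call kept. Immediate early and heat shock genes fell in 10 of 16 and rose in 3 (median -0.82, adjusted p = 0.0499, adjusted p = 0.661 with an estimated correlation). This call was lost after correction for GC content and length (adjusted p = 0.167), without H3.3WT replicate 2 (adjusted p = 0.116) and without H3.3K27M replicate 1 or 2 (adjusted p = 0.140 and 0.055). Adjusted over the list alone, 15 glycolysis genes rose and 1 fell, and 7 pluripotency markers rose and 3 fell. By the same adjustment 12 G2/M genes, 4 ribosomal protein genes and 3 nuclear oxidative phosphorylation genes rose, and 6 histone genes fell. Of the 82 Polycomb target regulators outside Hox, 24 were tested, with 10 lower and 3 higher. They did not pass as a list (median -0.40, adjusted p = 0.126). The PRC2 subunit and H3K27 demethylase lists also did not pass (medians 0.015 and -0.25, adjusted p = 0.306 and 0.724). Fatty acid oxidation genes had a median of -0.11 with the test pointing up (adjusted p = 0.824), and interferon-stimulated genes a median of -0.10 with the mean and the test pointing up (adjusted p = 0.632).

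Other large rises were Ier3 (8.99 ± 1.4 to 51.5 ± 5.1 FPKM), Spp1, which encodes osteopontin (2.05 ± 1.1 to 12.7 ± 2.2), the noncoding RNA Snhg5 (2.68 ± 0.53 to 15.9 ± 1.1), Ifitm1 (9.65 ± 1.3 to 43.0 ± 5.5), Tdgf1, which encodes a Nodal co-receptor (19.3 ± 2.4 to 78.6 ± 0.23), the endoplasmic reticulum chaperone gene Hsp90b1 (35.2 ± 3.7 to 139 ± 9.3) and Ogt, the O-GlcNAc transferase gene (2.86 ± 0.84 to 14.0 ± 3.7). Snord12 stood at 0.437 and 4.90 FPKM in H3.3WT and 11.4 and 11.8 in H3.3K27M, and its call was lost with robust variance estimates (adjusted p = 0.233) and without H3.3K27M replicate 1 or 2 (adjusted p = 0.075 and 0.114). Without H3.3WT replicate 1 its log2 change was 1.09, against 2.11. Among falls, Ier2 went from 269 ± 49 to 47.0 ± 6.7 FPKM, the stress-response gene Gadd45g from 41.4 ± 3.9 to 3.91 ± 1.4 and Spsb2 from 21.1 ± 4.6 to 2.73 ± 1.5. The mitochondrial tRNA genes mt-Tw, mt-Tm, mt-Ts1 and mt-Tv fell, with log2 changes of -3.37, -2.57, -2.52 and -2.39, and of -4.17 and -4.64 for mt-Ts1 and mt-Tv with a pseudocount of 0.1. H1fx stood at 103 and 120 FPKM in H3.3WT and at 39.8 in H3.3K27M replicate 1, and was listed at 0 in replicate 2, so its log2 change of -4.13 ± 1.31 (adjusted p = 0.048) rests on that library. The log2 change was -1.46 without H3.3K27M replicate 2 and -6.81 without replicate 1. Its call was lost without H3.3WT replicate 1 or 2 (adjusted p = 0.132 and 0.153), after correction for GC content and length (adjusted p = 0.101) and under most other settings.

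Of 11623 genes tested, 3049 differed, 979 higher and 2070 lower, and 987 changed by at least 1 on the log2 scale. The groups did not overlap for 66.3% of genes, where chance gives 33.3%. The median log2 change of all genes was -0.12. Median-of-ratios scaling brought it to 0.0053 and the share of higher calls from 32.1% to 49.3%. The count fell to 1007 without H3.3WT replicate 2, to 1206 without H3.3WT replicate 1 and to 1589 without H3.3K27M replicate 2.

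**Figure D3:**
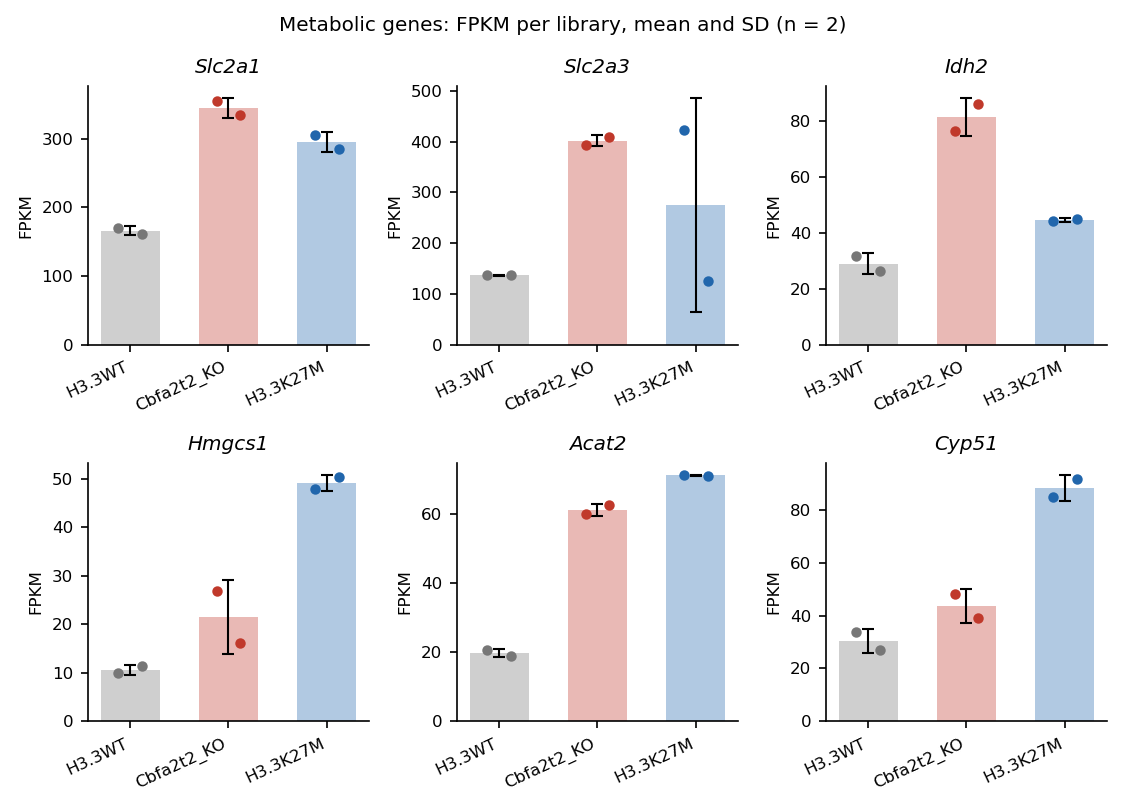
FPKM of 6 genes of glucose transport, the TCA cycle and sterol synthesis (y axes, starting at 0) in the 3 groups (x axes); points are libraries, bars the mean and error bars the SD of 2 libraries. Slc2a1 was 166, 344 and 295 FPKM in H3.3WT, Cbfa2t2_KO and H3.3K27M, and Slc2a3 differed between the H3.3K27M libraries (423.5 and 125.5).

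Changes in both lines against H3.3WT overlapped. Of 11403 genes tested in both, 537 were higher in both and 1454 lower in both. With median-of-ratios scaling these counts were 847 and 998, so the excess of shared lower genes depends on the scaling. Independent lists of the sizes as deposited would share 119 and 452. Simulations of unchanged groups against the same controls had means of only 1.15 to 1.53 calls per line and direction, too few to give an expected overlap. Fold changes correlated across genes with Pearson's r = 0.740, against a mean of 0.501 in 100 simulations without effects. The covariance was 0.254 against a simulated 0.0214, a difference of 0.233. The simulations drew each gene independently, without the trends across a library with GC content and exon number given below. The difference therefore does not measure an excess over such trends. With 1 H3.3WT library for each line, so that no control library was shared, the covariance was 0.243 and 0.220 in the 2 assignments and r was 0.677 and 0.583. The shared counts were then 206 higher and 550 lower, and 146 and 505, an alternative chosen after seeing the data. Differences common to both H3.3WT libraries remain in these values. The shared counts were 267 and 701 without H3.3WT replicate 1, and 176 and 564 without replicate 2.

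**Figure D4:**
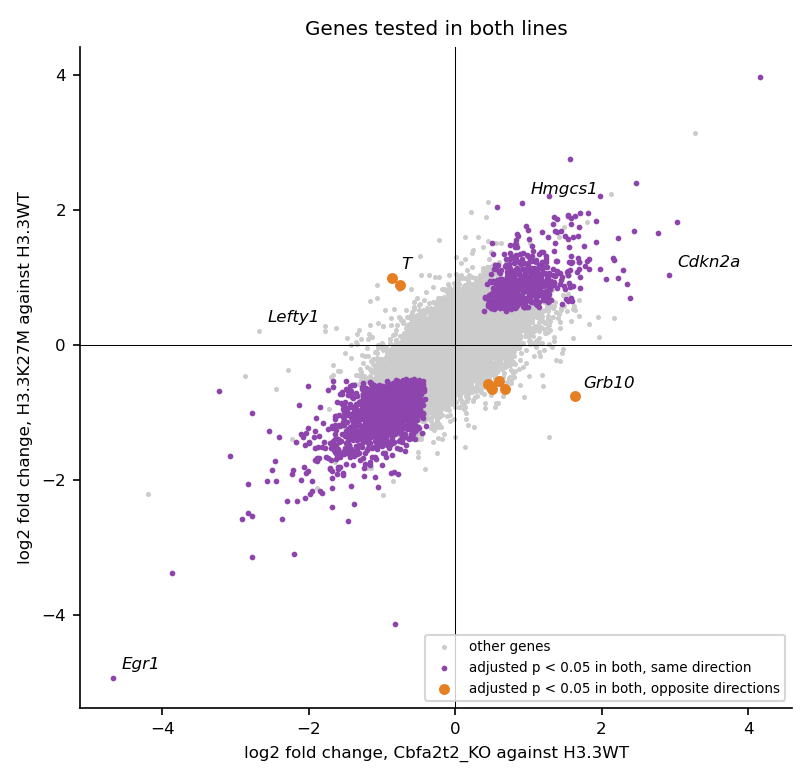
Log2 fold change of each gene tested in both lines, Cbfa2t2_KO against H3.3WT (x axis) and H3.3K27M against H3.3WT (y axis); colours mark genes past an adjusted p of 0.05 in both. In the same direction lay 537 higher and 1454 lower genes, and 8 genes lay in opposite directions.

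The third comparison set H3.3K27M against Cbfa2t2_KO directly, which tests whether the effects differ. In H3.3K27M 5 of 24 cholesterol biosynthesis genes, 4 of 13 pluripotency markers and 2 of 13 mitochondrially encoded genes were higher, and 4 of 11 replication-dependent histone genes were lower. The calls of these lists by camera were all lost with an estimated correlation (adjusted p = 0.740 with an estimated correlation), and that of the mitochondrially encoded genes also after correction for GC content and length (adjusted p = 0.226). Lefty1, an antagonist of Nodal signalling (chromosome 1, 180935022 to 180938400, forward strand), was 16.6 ± 0.59 FPKM in Cbfa2t2_KO and 129 ± 7.5 in H3.3K27M (log2 difference 2.89 ± 0.15, adjusted p = 0.00014). It was 112 ± 13 in H3.3WT, so the difference lay in Cbfa2t2_KO. Cdkn2a was 56.8 ± 4.9 FPKM in Cbfa2t2_KO and 14.9 ± 3.8 in H3.3K27M (log2 difference -1.88 ± 0.19, adjusted p = 0.0032). Grb10, an imprinted growth regulator (chromosome 11, 11930508 to 12038683, reverse strand), was 65.5 ± 8.6 and 11.8 ± 2.9 FPKM (log2 difference -2.39 ± 0.19, adjusted p = 0.0012).

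Ctgf (0.132 ± 0.0013 and 5.58 ± 0.040 FPKM), Tnnt1 (3.27 ± 0.49 and 21.9 ± 5.3), Stk39 (4.51 ± 0.51 and 20.9 ± 1.5) and Cox6a2 (3.97 ± 1.5 and 16.7 ± 1.4) were also higher in H3.3K27M than in Cbfa2t2_KO. Lingo3, Hip1r and Zcchc12 were lower, with log2 differences of -2.11, -1.85 and -1.77 and adjusted p between 0.0012 and 0.0032, and Lingo3 had -4.56 with a pseudocount of 0.1. In the cholesterol list 5 of 24 were higher and none lower (median 0.29, adjusted p = 0.0032, adjusted p = 0.740 with an estimated correlation). Cyp51, Sqle, which encodes squalene epoxidase, and Msmo1 stood at 43.7 ± 6.5, 25.4 ± 2.6 and 7.63 ± 1.8 FPKM in Cbfa2t2_KO and at 88.3 ± 4.8, 46.8 ± 4.5 and 22.7 ± 3.1 in H3.3K27M. All 3 calls were lost without Cbfa2t2_KO replicate 2 (adjusted p = 0.154, 0.171 and 0.162). That of Sqle was also lost without Cbfa2t2_KO replicate 1 (adjusted p = 0.055), and those of Cyp51 and Msmo1 without H3.3K27M replicate 2 (adjusted p = 0.064 and 0.089). Pluripotency and germ cell markers were higher in 4 of 13 (median 0.19, adjusted p = 0.0032, adjusted p = 0.740 with an estimated correlation), among them Tdgf1 (22.5 ± 2.5 and 78.6 ± 0.23 FPKM), Nanog (2.96 ± 0.15 and 9.23 ± 0.88) and Sall4 (8.03 ± 0.56 and 16.4 ± 3.5). The median of this list was 0.29 to 0.35 without any 1 library of the 2 groups compared and 0.33 after correction for GC content and length. Nanog and Sall4 lost their calls without Cbfa2t2_KO replicate 2 (adjusted p = 0.085 and 0.193), and Sall4 also without Cbfa2t2_KO replicate 1 (adjusted p = 0.071) or H3.3K27M replicate 1 (adjusted p = 0.073). Polycomb target regulators outside Hox were higher in 5 of 23 and lower in 1, Cdkn2a (median 0.25, adjusted p = 0.022, adjusted p = 0.740 with an estimated correlation). T, Eomes and Fgf8, mesoderm regulators at low levels, had log2 differences of 1.85, 1.35 and 1.03, with 2.17 and 1.88 for Eomes and Fgf8 at a pseudocount of 0.1. Eomes and Fgf8 lost their calls without Cbfa2t2_KO replicate 2 (adjusted p = 0.062 and 0.151), and Fgf8 also without replicate 1 (adjusted p = 0.057). The Polycomb target list lost its call with a mean FPKM minimum of 0.1 (adjusted p = 0.125) and without Cbfa2t2_KO replicate 1 (adjusted p = 0.139). Its median was 0.16 without Cbfa2t2_KO replicate 2 and 0.43 after correction for GC content and length.

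Mitochondrially encoded genes had a median of 0.65 with 2 of 13 past the threshold and 10 adjusted over the list alone (adjusted p = 1.3e-05, adjusted p = 0.740 with an estimated correlation). Both members, mt-Atp6 (81.2 ± 23 and 147 ± 0.82 FPKM, adjusted p = 0.043) and mt-Cytb (254 ± 62 and 423 ± 2.9, adjusted p = 0.048), lost their calls after correction for GC content and length (adjusted p = 0.273 and 0.289), as did the list (median 0.15, adjusted p = 0.226). Both genes also lost their calls without any 1 library of the 2 groups compared (adjusted p = 0.052 to 0.280 and 0.058 to 0.324) and under several other settings, and the list median was 0.41 without Cbfa2t2_KO replicate 2. The gene mt-Nd1 did not pass (297 ± 70 and 469 ± 5.2 FPKM, adjusted p = 0.060). G2/M genes (2 of 26 higher, median 0.29, adjusted p = 0.022, adjusted p = 0.798 with an estimated correlation) included Bub1 (12.3 ± 4.0 and 25.1 ± 1.9 FPKM) and Ttk (3.43 ± 1.3 and 7.34 ± 0.24), while Cenpf did not pass (1.32 ± 0.65 and 2.99 ± 0.98, adjusted p = 0.078). The list lost its call without Cbfa2t2_KO replicate 2 (median 0.16, adjusted p = 0.069) and without H3.3K27M replicate 1 (median 0.18). Bub1 and Ttk lost theirs without Cbfa2t2_KO replicate 2 (adjusted p = 0.197 and 0.253), H3.3K27M replicate 1 (adjusted p = 0.068 and 0.083) or H3.3K27M replicate 2. Ttk also lost its call without H3.3WT replicate 1 or 2 (adjusted p = 0.056 and 0.055) and after correction for GC content and length. No single hypoxia target passed, although the list did (median 0.32, adjusted p = 0.022, adjusted p = 0.740 with an estimated correlation), and its call was lost without Cbfa2t2_KO replicate 1 (adjusted p = 0.062) or H3.3K27M replicate 1 (adjusted p = 0.141). Ribosomal protein genes (2 of 34 higher, median 0.17, adjusted p = 0.032, adjusted p = 0.943 with an estimated correlation) lost their call under median-of-ratios scaling (adjusted p = 0.062) and without Cbfa2t2_KO replicate 1 (median 0.077, adjusted p = 0.476). Without H3.3K27M replicate 2 their median turned to -0.042 and the call was lost, and without replicate 1 it was 0.37. Replication-dependent histones were lower in 4 of 11 (median -0.52, adjusted p = 0.0067, adjusted p = 0.740 with an estimated correlation). Hist1h3d, Hist1h3c and Hist1h3a went from 6.91 ± 1.5, 16.1 ± 1.8 and 4.26 ± 0.10 FPKM in Cbfa2t2_KO to 2.80 ± 0.29, 6.89 ± 1.4 and 1.66 ± 0.54 in H3.3K27M. All 3 calls were lost without Cbfa2t2_KO replicate 2 (adjusted p = 0.177, 0.174 and 0.202). Those of Hist1h3c and Hist1h3a were also lost without Cbfa2t2_KO replicate 1 (adjusted p = 0.058 and 0.092) or H3.3K27M replicate 1 (adjusted p = 0.054 and 0.096), and those of Hist1h3d and Hist1h3a without H3.3K27M replicate 2 (adjusted p = 0.062 and 0.064). The histone list lost its call without H3.3K27M replicate 1 (adjusted p = 0.141) and had a median of -0.86 without H3.3K27M replicate 2 and a similar one without Cbfa2t2_KO replicate 1. Adjusted over the list alone, 7 cholesterol genes and 5 pluripotency markers were higher, and 9 Polycomb target regulators were higher and 2 lower. The median and the test differed in sign for fatty acid synthesis and desaturation (-0.077, adjusted p = 0.489), Wnt targets (-0.16, adjusted p = 0.831), astrocyte markers (-0.029, adjusted p = 0.431), interferon-stimulated genes (-0.066, adjusted p = 0.994) and TGF-beta and BMP targets (-0.00053, adjusted p = 0.810), where the mean and the test pointed up. Serine, glycine and one-carbon genes had a median of 0.023 and a mean of -0.0074, with the test pointing up (adjusted p = 0.810). The glycolysis list did not differ by this test (median -0.012, adjusted p = 0.877).

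Of 11601 genes, 905 differed between H3.3K27M and Cbfa2t2_KO, 362 higher and 543 lower, and 232 by at least 1 on the log2 scale. The excess of lower genes turned round when either Cbfa2t2_KO replicate was left out. The groups did not overlap for 58.2% of genes, where chance gives 33.3%. Fold changes in this comparison moved with GC content, as given below. After correction for GC content and length, 695 of the 905 calls were kept. Leaving out a library lowers power, and this was not told apart from the influence of single libraries. The H3.3WT libraries do not enter the difference itself, yet leaving out either also lowered the number of calls. The median log2 change of all genes stayed at -0.019 and -0.020 there, against -0.019 with all libraries. The count of 905 fell when single libraries were left out. It was 29 without Cbfa2t2_KO replicate 2, 162 without Cbfa2t2_KO replicate 1, 161 without H3.3K27M replicate 2, and 564 and 582 without H3.3WT replicate 1 and 2. Of the 848 of these genes tested against H3.3WT in both lines, 394 had been called in Cbfa2t2_KO alone, 199 in H3.3K27M alone, 100 in both and 155 in neither.

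Fold changes against H3.3WT moved with exon number in both lines. Protein-coding genes with 1 to 3 exons had a median log2 change of -0.39 in Cbfa2t2_KO (1218 genes) and -0.44 in H3.3K27M (1209 genes), against -0.065 and -0.10 for genes with 6 or more exons. Immediate early genes, described above as lower in both lines, have few exons. So have the replication-dependent histone genes, which were lower as a list in H3.3K27M. In Cbfa2t2_KO that list had a median of 0.075 and did not pass camera (adjusted p = 0.685). Fold changes also moved with GC content, by -0.31 on the log2 scale per 10 percentage points in H3.3K27M against Cbfa2t2_KO. Against H3.3WT the slope was -0.27 for H3.3K27M and 0.037 for Cbfa2t2_KO. The value for Cbfa2t2_KO averages libraries that differed. Against H3.3WT replicates 1 and 2 the slope was -0.16 and -0.015 for Cbfa2t2_KO replicate 1, and 0.088 and 0.23 for replicate 2.

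**Figure D5:**
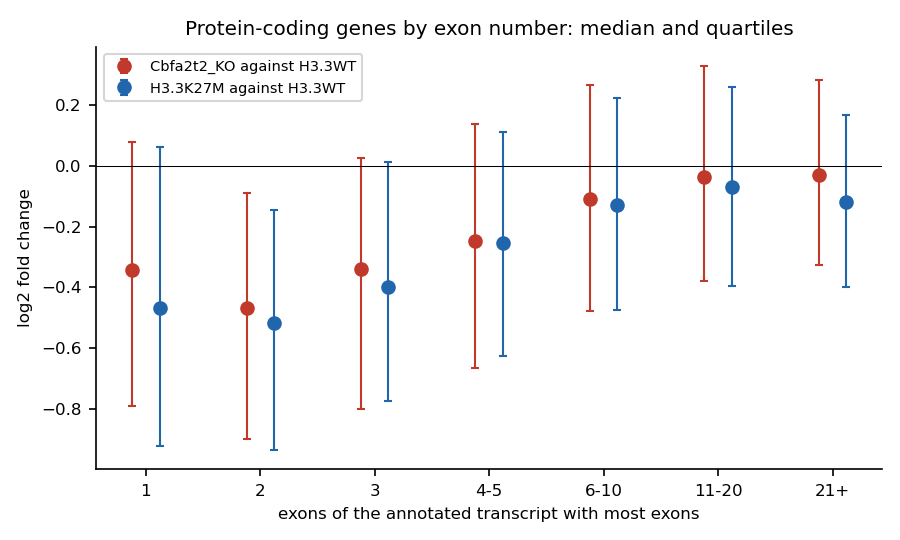
Median log2 fold change against H3.3WT (y axis) of protein-coding genes by exon number (x axis, the annotated transcript with most exons) in Cbfa2t2_KO and H3.3K27M; error bars span the quartiles of genes. Genes with 2 exons had medians of -0.47 and -0.52, and genes with 11 to 20 exons -0.035 and -0.071.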

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

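The tests of the exon, GC content and pluripotency patterns in this part were chosen after the result was seen. For 8 genes, both lines differed from H3.3WT in opposite directions. Because these genes were picked for opposite calls against the same controls, a difference between H3.3K27M and Cbfa2t2_KO was all but fixed, and the direct test adds no separate evidence. Grb10 rose in Cbfa2t2_KO (log2 change 1.63) and fell in H3.3K27M (-0.76), a log2 difference of -2.393. Lypd1 fell in Cbfa2t2_KO and rose in H3.3K27M, with a difference of 1.633, as did T, with 1.854. The other genes were higher in Cbfa2t2_KO and lower in H3.3K27M, with differences of -1.139 for Grn, -1.147 for Pink1, -1.114 for Acaa2, -1.332 for Gm13597 and -1.024 for Alox15. Without H3.3WT replicate 1 a single gene was called in opposite directions, and without H3.3WT replicate 2 the count was 0.

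Protein-coding genes with 1 to 3 exons were lower than those with 6 or more in both lines against H3.3WT, by a difference of medians of -0.325 in Cbfa2t2_KO and -0.341 in H3.3K27M (log2). A bias by GC content or length is argued against, since the differences were -0.347 and -0.358 after its correction. Genomic DNA or another constant background in the H3.3WT libraries is argued against too, since abundant genes, of at least 30 FPKM, kept differences of -0.437 and -0.330. A difference in handling of the H3.3WT libraries stays open and cannot be told apart from a change shared by both lines, because H3.3WT is in both comparisons and the difference between H3.3K27M and Cbfa2t2_KO was 0.0438. Between the libraries of a group the differences were 0.0763, 0.111 and 0.174.

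GC-rich genes were lower in H3.3K27M than in H3.3WT, with a slope of -0.269 on the log2 scale per 10 percentage points. They were also lower than in Cbfa2t2_KO, with a slope of -0.306, so the pattern was not limited to the comparison with H3.3WT. A GC bias that differs from library to library may account for the pattern and stays open. The Cbfa2t2_KO libraries differed from each other by a slope of 0.249 and the H3.3WT libraries by -0.146. The H3.3K27M libraries differed by -0.0017, so a shared effect of the H3.3K27M line, named by the design and not tested apart from the libraries, stays open as well.

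Some pluripotency transcripts were abundant in every library of a line labelled as neural stem cells: Pou5f1 stood at 919 to 1351 FPKM, Utf1 at 162 to 449 and Lin28a at 166 to 234. Others were low, with Nanog at 2.85 to 9.86, Klf4 at 0.703 to 1.60 and Dppa5a at 0 to 0.767, and the neural markers Sox3, Id1, Sox2 and Nes stood at 47.4 to 92.9, 38.6 to 131, 9.55 to 34.4 and 14.3 to 38.8. Over the lists, 4 of 16 pluripotency and 6 of 21 neural markers had at least 10 FPKM in all libraries, with medians of 2.96 and 7.18 FPKM. So had 4 of 9 astrocyte (8.39), 3 of 12 epithelial (5.38), 4 of 17 mesenchymal (2.96), 2 of 13 neuronal (2.75) and 1 of 4 oligodendrocyte markers (1.14). At least 100 FPKM in all libraries was reached by 3 pluripotency markers, 1 astrocyte marker and 0 of the others, while some others, such as Id1, passed 100 in some libraries. Abundant markers moved apart in Cbfa2t2_KO against H3.3WT, from 0.42 for Lin28a to -1.20 for Utf1, a spread of 1.618 ± 0.21. The SE takes no account of picking the highest and lowest marker. This spread argues against pluripotent cells mixed in at different shares only where such a change would move all markers alike. A marker also made in other cells, or changed within the cells, would move apart too. Different or constant shares of such cells and the identity of the line stay open.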

How the results depend on the processing

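The corrections for GC content, length and exon number and the separate controls were chosen after seeing the data; the other alternatives were chosen before. Where an arm was left with 1 library, that library was assumed to vary like the others. Over alternatives other than leaving out a replicate, 122 counts stayed within 1.5 times their value and 18 did not. Over these alternatives 12 list calls and 26 gene calls were lost. The 12 do not take in fry or camera with an estimated correlation, and the latter lost every list call. The cause of these moves was not tested, and fewer libraries or a stricter minimum can lower a count in themselves. The edgeR and DESeq2 alternatives were not run, because the tables hold no counts. Unknown depth leaves counting error out of every statement.

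With a log2 change of at least 1, 1073 genes changed in Cbfa2t2_KO and 987 in H3.3K27M against H3.3WT. For H3.3K27M against Cbfa2t2_KO, correction for GC content and length gave 554 higher genes, and with exon number 1400 changed and 630 higher. An estimated correlation called 0 lists in Cbfa2t2_KO, 0 in H3.3K27M and 0 in the direct comparison, where fry called 0 in H3.3K27M and 3 in the direct comparison. Genes higher in both lines numbered 847 with median-of-ratios scaling, and lower in both 998. Genes in opposite directions numbered 13 with all 6 libraries in the fit and 21 with GC and length correction.

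H3f3b passed in Cbfa2t2_KO with quantile normalization (-0.41) and GC and length correction (-0.34). In H3.3K27M it passed with a minimum of 5 FPKM (-0.54), quantile normalization (-0.63), GC and length correction (-0.79), exon number added (-0.70) and all 6 libraries (-0.54). Against Cbfa2t2_KO it passed with GC and length correction (-0.45) and exon number added (-0.44). Cbfa2t2 in H3.3K27M against H3.3WT, not called, turned to -0.043 with a pseudocount of 0.1.

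Leaving out each replicate gave 1915 (without Cbfa2t2_KO replicate 2) to 3038 changed genes in Cbfa2t2_KO, 710 to 1170 higher and 1205 to 1868 lower. It gave 1007 (without H3.3WT replicate 2) to 2790 in H3.3K27M, 295 to 811 higher and 712 to 1979 lower, and 29 (without Cbfa2t2_KO replicate 2) to 786 in the direct comparison, 19 to 266 higher and 10 to 520 lower. Lists called in the direct comparison numbered 5 to 11. The overlap was recomputed only without each H3.3WT replicate, where genes higher in both lines numbered 176 to 267, lower in both 564 to 701, and in opposite directions 0 to 1. With separate controls, H3.3WT replicate 1 for Cbfa2t2_KO and 2 for H3.3K27M gave 206 higher in both, 550 lower and 6 opposite (r = 0.677 across genes), and the reverse gave 146, 505 and 4 (r = 0.583). The median of nuclear oxidative phosphorylation genes in H3.3K27M ran from -0.040 (without H3.3K27M replicate 2) to 0.32, and that of ribosomal proteins in the direct comparison from -0.042 (without H3.3K27M replicate 2) to 0.37. Cbfa2t2 ran from -0.35 to 0.35 in H3.3K27M against H3.3WT and from -0.028 to 0.67 in the direct comparison. H3f3a ran from -1.32 to -0.86 in H3.3K27M against H3.3WT, and from -0.19 to 0.11 in the direct comparison.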

Other observations

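Endoplasmic reticulum chaperone genes and ribosome biogenesis genes were seen among the largest changes, and lists of both were then chosen after seeing the data, leaving out the members already seen. The tests on the remaining members were chosen before their values were seen. Hspa5, which encodes the chaperone BiP, rose from 98.5 ± 14 to 257 ± 38 FPKM in Cbfa2t2_KO and to 234 ± 7.7 in H3.3K27M (SD, n = 2). Calr, which encodes calreticulin, rose from 181 ± 11 to 529 ± 15 and 285 ± 8.5 FPKM. Of 25 chaperones and folding factors tested in Cbfa2t2_KO, 18 rose and 1 fell (median log2 change 0.678, camera adjusted p = 1.5e-08, adjusted p = 0.0805 with an estimated correlation). Of 24 tested in H3.3K27M, 4 rose (median 0.380, camera adjusted p = 0.000105, adjusted p = 0.0805 with an estimated correlation). Without H3.3WT replicate 1, 11 rose in Cbfa2t2_KO and 1 in H3.3K27M. In H3.3K27M 2 rose without H3.3WT replicate 2, and 7 without H3.3K27M replicate 1, while 8 rose with median-of-ratios scaling and 9 rose and 2 fell after correction for GC content, length and exon number. In the direct comparison, adjusted over both lists, this list was lower in H3.3K27M than in Cbfa2t2_KO (median -0.35, 3 genes lower, camera adjusted p = 0.000437, adjusted p = 0.0539 with an estimated correlation). None was lower without Cbfa2t2_KO replicate 1, Cbfa2t2_KO replicate 2 or H3.3K27M replicate 2, 2 were without either H3.3WT replicate, and 7 were after correction for GC content, length and exon number. A joint rise may be a hypothesis for Cbfa2t2_KO, while in H3.3K27M it rests on the median of the list, since the number of members that passed depended on these settings.

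Among ribosome biogenesis factors, Nip7 fell from 76.9 ± 6.9 to 24.9 ± 2.5 FPKM in Cbfa2t2_KO and to 33.2 ± 3.7 in H3.3K27M, and Bysl from 47.1 ± 0.34 to 19.4 ± 1.1 and 20.2 ± 0.19. Of 37 members, 22 fell in Cbfa2t2_KO (median -0.592, camera adjusted p = 2.3e-05, adjusted p = 0.0805 with an estimated correlation). In H3.3K27M 12 fell and 1, Npm1, rose (median -0.361, camera adjusted p = 0.0408, adjusted p = 0.140 with an estimated correlation). The H3.3K27M call was lost with median-of-ratios scaling (median -0.21), without H3.3WT replicate 1 (median -0.28) and without H3.3K27M replicate 1 (median -0.35), where camera did not pass at an unadjusted threshold of 0.05. In Cbfa2t2_KO 12 fell without Cbfa2t2_KO replicate 2. In H3.3K27M 3 fell without H3.3WT replicate 1, 5 without H3.3WT replicate 2 and 5 without H3.3K27M replicate 2, with 6 under median-of-ratios scaling and 19 after correction for GC content, length and exon number. That correction gave medians of -0.73 and -0.45. Against Cbfa2t2_KO the list was higher in H3.3K27M (median 0.19, 4 genes higher, camera adjusted p = 0.000687, adjusted p = 0.0539 with an estimated correlation). None was higher without Cbfa2t2_KO replicate 2 or H3.3K27M replicate 2, 2 were without any 1 of the other 4 libraries, and 8 were higher and 1 lower after correction for GC content, length and exon number. A joint fall of these genes may be a further hypothesis for Cbfa2t2_KO.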
